A study of Mus musculus with 22 samples.

How the data were processed

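The samples were lung RNA of C57BL/6 mice from the caudal lobes of the right lung, in 4 groups and 22 libraries. Per the labels, polyadenylated RNA was selected from 400 ng of total RNA, stranded libraries were made, 24 libraries were pooled per run, and single ends were read for 75 cycles. The labels name the arms by sensitisation with OVA or saline, while the protocol text can also be read as a saline challenge of sensitised mice, and the arms are therefore called the saline arm and the OVA arm. The design text gives 5 samples per group, and the groups without PM held 6 libraries each. Reads were converted with bcl2fastq and placed on mm10 per the submitters' processing notes, and the aligner and the counting tool were not given in the sources used here.

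The authors deposited 3 tables of raw read counts per gene, and these counts were used for all tests. The authors also deposited 3 tables of their own statistics, with log2 fold changes and adjusted p-values per the file headers, which were compared with the present calls and used for nothing else. The normalised values in the deposited workbooks differed in scale between workbooks and were not used here. The count tables shared 12 library columns, and 12 of these were identical between tables. Of 24421 gene rows, 16 had names turned into dates by a spreadsheet, which held 0.152% to 0.195% of a library's counts, and they were left out, so that 24405 were used. Of the gene names, 23361 were matched to GENCODE M21 (GRCm38) for positions, transcript lengths and GC content.

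Library totals ran from 0.302 M to 28.01 M counts, with a median of 12.5 M. No 2 replicates were near copies of each other, since the chi-square per degree of freedom between replicates was 2.58 to 81.5 on genes with at least 10 counts.

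Groups were compared pairwise, each with its own filter and fit, and the PM effects of the 2 arms were compared in a fit of all 4 groups. Genes were kept by edgeR's expression filter (minimum count 10, minimum total count 15), scaled by trimmed means of M values (TMM) and tested with edgeR's quasi-likelihood F test. The Benjamini-Hochberg method was applied per comparison at 0.05. Standard errors of log2 fold changes were taken as the log2 fold change divided by the square root of F. Levels are given as CPM, counts scaled to a common library size by TMM, and log2 CPM values used a prior count of 2. The 47 gene lists were fixed from general knowledge before the data were examined, as were the groups, the comparisons and the alternatives marked below. Lists with at least 3 tested genes were tested with camera (limma) with a preset correlation of 0.01 between genes, which left 45 lists per comparison, again with an estimated correlation, and with fry. For each list the genes past the threshold over all genes and adjusted over the list alone were counted.

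Genes named in the text came from a fixed rule. They were the 8 largest changes each way among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups' libraries (5 each way for the difference between the arms, without the overlap part), up to 3 members with the smallest p of up to 8 called lists, and 11 genes fixed beforehand. Predicted loci and immunoglobulin and T cell receptor segments were left out of the rule, and genes chosen after their values were seen are stated as such.

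The alternatives were DESeq2, DESeq2 size factors in edgeR, scaling by library totals, no filter, a filter of 1 CPM in 5 libraries, all 4 groups in one fit, replicate numbers as a block, and leaving out each library in turn. Not fixed then, and chosen after results were seen, were an offset for transcript length and GC content (natural splines with 4 degrees of freedom per library, on genes with a mean of at least 10 CPM) and leaving out the libraries under 2 M counts. Each comparison was also repeated on 100 splits of the same libraries into groups of the same sizes, the real one included. Slopes of log2 CPM on length and GC per library were compared by exact permutation tests.

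The procedure was tested on simulated counts with the depths and dispersions of these libraries, 200 changed genes and 1 changed list. Camera called that list in each comparison and 0 other lists. The 31 lists held random genes drawn independently of each other, so that this does not test the preset correlation. At a log2 fold change of 1 the procedure recovered 89% (OVA without PM), 94% (PM in the saline arm), 80% (PM in the OVA arm), 89% (OVA with PM) and 75% (difference between the arms) of the planted genes. False calls made up 5.58%, 4.21%, 4.00%, 9.38% and 3.78% of the calls, so that the rates for OVA without PM and OVA with PM lay above the nominal 5%. A planted length slope of -0.15 with no changed gene called 12, 5, 19, 138 and 6 genes without the offset, and 0, 0, 0, 6 and 0 with it.

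The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.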

Results

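Polyadenylated RNA was sequenced from the caudal lobes of the right lung of C57BL/6 mice in a model of allergic airway disease. The labels give 4 groups, which cross sensitisation with the allergen ovalbumin (OVA) or saline with exposure to 3 µg of particulate matter (PM) from a goat farm or no PM. There were 6 libraries in the saline arm without PM, 5 in the saline arm with PM, 6 in the OVA arm without PM and 5 in the OVA arm with PM. The deposited gene counts summed to between 0.302 M (OVA arm with PM, replicate 4) and 28.01 M (saline arm with PM, replicate 5) per library, with a median of 12.5 M. The group medians were 14.5 M and 10.3 M in the saline arm without and with PM, and 13.7 M and 10.3 M in the OVA arm without and with PM. Besides the shallowest library, replicate 5 of the OVA arm with PM (1.13 M) and replicate 4 of the OVA arm without PM (1.84 M) held fewer than 2 M counts. The labels do not state that the libraries came from separate animals, so that all p-values measure the spread between these samples, which may be technical. The libraries with PM carry another series of sample numbers in the labels than those without PM, and a difference in preparation or sequencing run between them cannot be told apart from PM within an arm.

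The first comparison asked how the lungs of the OVA arm differed from those of the saline arm in the absence of PM. Among the genes with large rises were several of mucus-producing and alternatively activated cells. Muc5ac, the main inducible airway mucin, rose from 1.47 ± 0.782 CPM (SD, n = 6) to 169 ± 86.4 CPM (SD, n = 6), a log2 fold change of 7.13 ± 0.60 (SE, edgeR adjusted p = 3.49e-06). Mrgprg, a receptor of the Mas-related family, held 2 counts over the 6 libraries of the saline arm and 420 over those of the OVA arm (edgeR adjusted p = 1.65e-05). Rises of similar size to that of Muc5ac were seen in Rnase2a, an eosinophil-type ribonuclease (7.03 ± 0.62, edgeR adjusted p = 4.57e-06), and in Capn9, a calpain of digestive epithelia (6.88 ± 0.73, edgeR adjusted p = 1.63e-05). Clca1, a secreted regulator of goblet cells, rose from 42.3 ± 51.5 CPM to 4695 ± 2306 CPM (log2 fold change 6.83 ± 0.97, edgeR adjusted p = 0.000163). The chitinase-like Chil4 rose from 4.48 ± 5.17 CPM to 611.8 ± 380 CPM (log2 fold change 7.48 ± 1.08, edgeR adjusted p = 0.000191). Retnla, a marker of alternatively activated macrophages, rose from 173 ± 147 CPM to 9075 ± 4453 CPM (log2 fold change 5.73 ± 0.61, edgeR adjusted p = 1.78e-05). The chemokine gene Ccl8 rose from 7.06 ± 3.06 CPM to 386 ± 101 CPM (log2 fold change 5.85 ± 0.29, edgeR adjusted p = 4.05e-08). Ccl11, which encodes the eosinophil attractant eotaxin, rose from 3.65 ± 0.608 CPM to 43.4 ± 18.9 CPM (log2 fold change 3.60 ± 0.33, edgeR adjusted p = 6.14e-06). In the GRCm38 (mm10) assembly with the GENCODE M21 annotation, these protein-coding genes lie at 141788972 to 141819231 on chromosome 7 (Muc5ac), 145003817 to 145032776 on chromosome 3 (Clca1), 106201490 to 106219507 on chromosome 3 (Chil4), 48842551 to 48844461 on chromosome 16 (Retnla) and 82115185 to 82116799 on chromosome 11 (Ccl8).

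**Figure D1:**
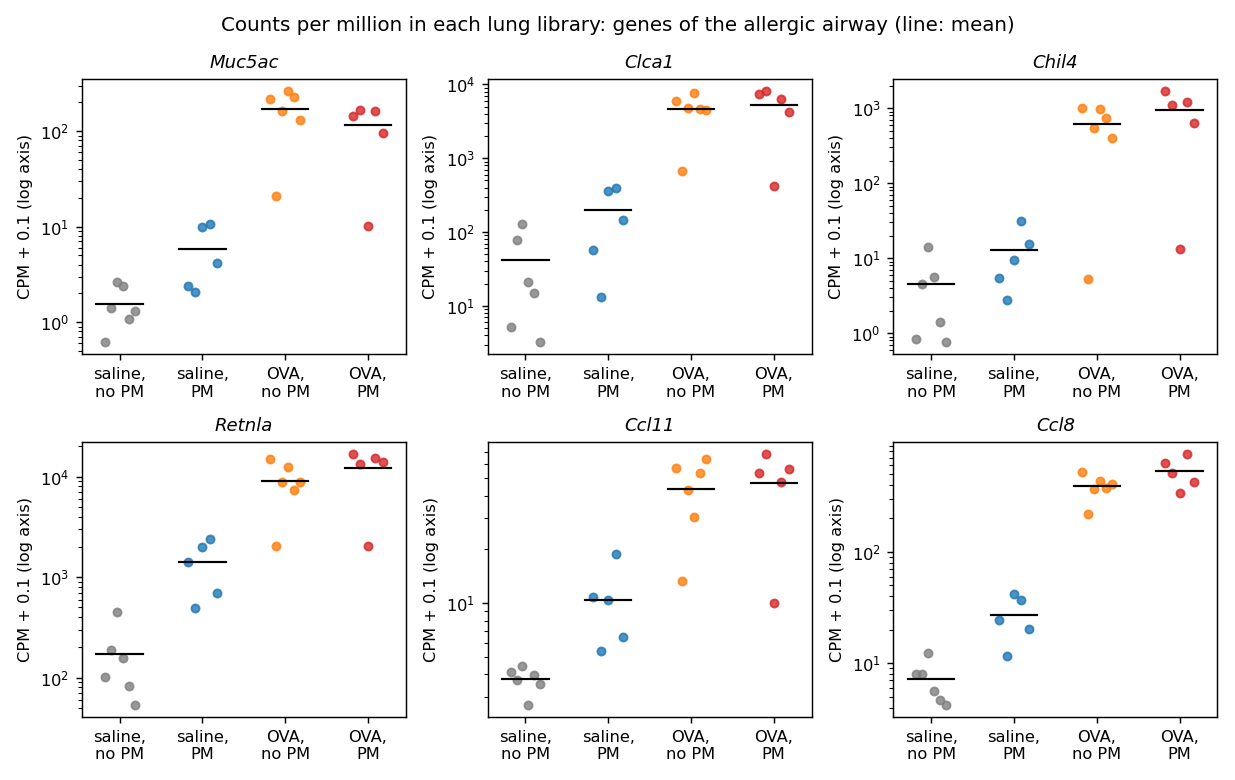
TMM-scaled counts (CPM, log axis, with 0.1 added) of Muc5ac, Clca1, Chil4, Retnla, Ccl11 and Ccl8 in each of the 22 libraries, by group, with a line at each group's mean. Muc5ac averaged 169 CPM in the OVA arm without PM and 1.47 CPM in the saline arm without PM. Single libraries of both OVA groups lie far below the others, at 21.03 CPM (replicate 2 without PM) and 9.95 CPM (replicate 4 with PM, 3 counts).

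All 12 measured mucous cell genes rose, and so did all 12 adjusted over the list alone, among them Slc26a4, the anion exchanger pendrin (log2 fold change 4.61), and Fcgbp, a mucus protein (4.44). The list was called by camera, and its call was lost with adjusted p = 0.0634 with an estimated correlation. All 12 alternatively activated macrophage and chitinase-like genes rose (12 adjusted over the list alone; adjusted p = 0.0634 with an estimated correlation). Of 13 monocyte and interstitial macrophage markers 10 rose, 11 adjusted over the list alone, including the complement genes C1qa (log2 fold change 1.93), C1qb (2.13) and C1qc (1.90). This list held its call (adjusted p = 0.00248 with an estimated correlation). Each of the 18 proliferation genes rose, 18 adjusted over the list alone, such as Top2a (log2 fold change 2.94), Ccnb1 (3.47) and Cdc20 (2.07), which act in DNA untangling and mitosis (adjusted p = 0.0542 with an estimated correlation). Of 24 interferon-stimulated genes 22 rose, 23 adjusted over the list alone, with Irf7 at a log2 fold change of 1.82 and Zbp1 at 1.94 (adjusted p = 0.0542 with an estimated correlation). B cell markers rose in 12 of 12 cases (12 adjusted over the list alone), with Blk at 1.33 and Fcer2a, the low-affinity IgE receptor, at 1.23 (adjusted p = 0.0582 with an estimated correlation). All 10 genes of MHC class II presentation rose, 10 adjusted over the list alone, with the master regulator Ciita at 1.36 (adjusted p = 0.0634 with an estimated correlation). T cell markers rose in 11 of 14 cases, 12 adjusted over the list alone (adjusted p = 0.0634 with an estimated correlation). Eosinophil markers rose in 6 of 9 cases, 7 adjusted over the list alone (adjusted p = 0.174 with an estimated correlation).

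NF-kB-driven cytokines and neutrophil chemoattractants rose in 11 of 17 cases, 12 adjusted over the list alone, with Cxcl3 at a log2 fold change of 3.73, Ccl2 at 3.34 and Cxcl1 at 2.63 (adjusted p = 0.0542 with an estimated correlation). Saa3, an acute-phase gene of the lung, rose by a log2 fold change of 4.35 ± 0.36 (edgeR adjusted p = 3.49e-06). Of 13 neutrophil markers 2 rose and 11 did not pass (2 rose adjusted over the list alone), and S100a8, a neutrophil calprotectin gene, had a log2 fold change of -0.30 ± 0.30 (edgeR adjusted p = 0.517). Chil3, a chitinase-like gene, rose by 4.03 ± 0.68 (edgeR adjusted p = 0.000665). Cyp1a1, a target of the aryl hydrocarbon receptor, fell (-0.66 ± 0.20, edgeR adjusted p = 0.0294), but did not pass without replicate 1, 2 or 4 of the saline arm without PM (-0.60, -0.61 and -0.59) or replicate 2, 3, 5 or 6 of the OVA arm without PM (-0.58, -0.61, -0.65 and -0.68). Alveolar type 1 cell markers fell in 8 of 12 cases, 11 adjusted over the list alone (adjusted p = 0.244 with an estimated correlation), and endothelial markers in 7 of 13, 7 adjusted over the list alone (adjusted p = 0.21 with an estimated correlation). Genes with large falls were Asgr1, a lectin receptor (log2 fold change -2.37 ± 0.43), Pon1, an esterase (-1.86 ± 0.35), and Gdpd2 (-1.84 ± 0.34). In all, edgeR's quasi-likelihood test called 3456 of 14632 genes, 2100 higher and 1356 lower in the OVA arm, and 780 of the higher and 52 of the lower genes differed by more than a log2 fold change of 1. The lower genes numbered 830 without replicate 6 and 860 without replicate 1 of the OVA arm without PM. Camera with a preset correlation between genes called 25 of 45 lists, of which 1 held with an estimated correlation, and the list calls here and below rest mostly on that preset value. DESeq2 called 3941 genes, and 3405 of the edgeR calls were among them with the same sign.

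The next comparison asked what PM did in the saline arm. Saa3, an acute-phase gene, rose from 7.97 ± 2.68 CPM (SD, n = 6) to 338.8 ± 178 CPM (SD, n = 5), a log2 fold change of 5.47 ± 0.39 (SE, edgeR adjusted p = 6.87e-06). Cxcl3, a neutrophil chemoattractant, rose from 0.613 ± 0.264 CPM to 17.4 ± 6.11 CPM (log2 fold change 4.72 ± 0.30, edgeR adjusted p = 2.14e-06). Lcn2, an iron-sequestering defence protein, rose from 256 ± 70.5 CPM to 1511 ± 535 CPM (log2 fold change 2.58 ± 0.24, edgeR adjusted p = 6.49e-05). The acute-phase gene Orm2 stood at 0.0414 ± 0.0817 CPM without PM, 5 counts over the 6 libraries, and at 8.84 ± 4.79 CPM with PM (edgeR adjusted p = 3.07e-05). Irg1, which makes the antimicrobial metabolite itaconate, rose by a log2 fold change of 4.59 ± 0.36 (edgeR adjusted p = 1.37e-05). In the GRCm38 assembly Saa3 lies at 46711998 to 46715700 on chromosome 7, Cxcl3 at 90786103 to 90789600 on chromosome 5 and Orm2 at 63362449 to 63365878 on chromosome 4.

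NF-kB-driven cytokines and neutrophil chemoattractants rose in 12 of 17 cases with PM in the saline arm, 13 adjusted over the list alone, with Cxcl2 at a log2 fold change of 2.89, Ccl3 at 2.10 and Cxcl1 at 2.03 (adjusted p = 0.0744 with an estimated correlation). Secreted defence proteins of airway epithelium rose in 6 of 11 cases, 8 adjusted over the list alone, including Saa1 (log2 fold change 3.52) and Pigr, the transporter of secreted IgA (1.35) (adjusted p = 0.147 with an estimated correlation). Among 19 receptors and adaptors of microbial products 7 rose and 1 fell (11 rose and 1 fell adjusted over the list alone), with the receptors Clec4e at 1.92, Clec4d at 1.47 and Tlr1 at 0.72 (adjusted p = 0.147 with an estimated correlation). Alternatively activated macrophage and chitinase-like genes rose in 6 of 12 cases, 11 adjusted over the list alone, with Retnla at 3.04 ± 0.53 and Ccl8 at 1.98 ± 0.33 (adjusted p = 0.166 with an estimated correlation). Mucous cell genes rose in 5 of 11 cases, 9 adjusted over the list alone, with Agr2, a mucin-folding isomerase, at 2.17 and Muc5ac at 2.21 ± 0.47 (adjusted p = 0.289 with an estimated correlation). Muc5ac no longer passed without replicate 5 of the saline arm with PM, at a log2 fold change of 1.67. Clca1 (2.27 ± 0.89, edgeR adjusted p = 0.0987) and Chil4 (2.02 ± 0.73, edgeR adjusted p = 0.0747) did not pass, and did pass without replicate 3 of the saline arm without PM, at 2.99 and 2.82. Unfolded protein response genes rose in 9 of 13 cases (9 adjusted over the list alone), such as the chaperone gene Hspa5 (log2 fold change 0.45) and Sdf2l1, of a chaperone complex of the endoplasmic reticulum (0.67) (adjusted p = 0.181 with an estimated correlation). Ccl11 rose by 1.53 ± 0.28 (edgeR adjusted p = 0.00843). Chil3 (0.98 ± 0.35, edgeR adjusted p = 0.0715) and Cyp1a1 (-0.47 ± 0.20, edgeR adjusted p = 0.115) did not pass, and did pass without replicate 3 of the saline arm without PM, at 1.45 and -0.54. S100a8 (0.38 ± 0.20, edgeR adjusted p = 0.196) did not pass, passed without replicate 4 of that group at 0.55, and stood at -0.10 with the length and GC offset.

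Endothelial markers fell with PM in 8 of 13 cases in the saline arm, 10 adjusted over the list alone (adjusted p = 0.166 with an estimated correlation). Smooth muscle markers fell in 4 of 9 cases, 8 adjusted over the list alone (adjusted p = 0.431 with an estimated correlation), and heart muscle genes in 2 of 12, 9 adjusted over the list alone, at a median log2 fold change of -1.01 (adjusted p = 0.544 with an estimated correlation). Single genes with large falls were Nos2, the inducible nitric oxide synthase (-1.21 ± 0.23), Spry4, an inhibitor of growth factor signalling (-1.21 ± 0.21), and the potassium channel gene Kcnh1 (-1.05 ± 0.19). The median transcript length of the genes called lower was 4169 nt, against 2643 nt for those called higher and 3292 nt for those not called. The libraries differed in their slope of log2 CPM on GC content, which averaged -0.133 ± 0.128 per 10 points of GC with PM (SD, n = 5) and 0.118 ± 0.126 without (SD, n = 6; exact permutation test, two-sided, p = 0.00649, 0.0405 adjusted over 8 such tests). Their slope on transcript length averaged -0.0728 ± 0.0115 per doubling with PM (SD, n = 5) and 0.0750 ± 0.160 without (SD, n = 6; exact permutation test, p = 0.0758, adjusted p = 0.152).

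Between the groups with and without PM of the saline arm, edgeR's test called 1862 of 14496 genes, 793 higher and 1069 lower with PM. Camera called 24 of 45 lists, 0 of which held with an estimated correlation (9 of the 45 lists at an unadjusted p under 0.05, and 18 past the threshold by fry). The gene count rested on single libraries. It was 4112 without replicate 3 and 2946 without replicate 4 of the saline arm without PM, and 713, 579 and 586 without its replicates 2, 5 and 6, while without its replicate 1 the higher genes numbered 491. Without replicates 1, 2, 3, 5 and 6 of the saline arm with PM it was 568, 677, 744, 490 and 1171. With each library's trend on transcript length and GC entered as an offset, 1323 genes were called, 619 higher and 704 lower, and 867 of the 1862 kept their call.

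The PM effect in the saline arm was also set beside the OVA effect without PM, which uses the same 6 control libraries. Of the genes tested in both, 435 were higher and 234 lower in both, where independent lists would share 110 and 100, and 30 were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had r = 0.512 and a covariance of 0.0952. In 20 simulations of unchanged groups against shared controls r averaged 0.475 and the covariance 0.0124. Genes were drawn independently there and without the length and GC trend. The shared calls were 0, which follows from no gene being changed, so that they set no baseline for the shared counts above. With the controls split, r was 0.451 and 0.483 and the covariance 0.0952 and 0.0983, with 204 genes higher in both in the first split (independent lists 43.5) and 57 in the second (independent lists 6.68), and 42 (28.1) and 6 (1.14) lower in both.

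The comparison within the OVA arm asked what PM did in lungs of mice that were also given the allergen. The 11 genes fixed beforehand did not pass the test. Muc5ac stood at 169 ± 86.4 CPM (SD, n = 6) without and 115.4 ± 65.5 CPM (SD, n = 5) with PM, a log2 fold change of -0.42 ± 0.47 (SE, edgeR adjusted p = 0.595). Clca1 had a log2 fold change of 0.15 ± 0.56 (edgeR adjusted p = 0.901), Il13, the cytokine that drives mucus production, 0.20 ± 0.55 (edgeR adjusted p = 0.856), Ccl11 0.28 ± 0.32 (edgeR adjusted p = 0.597), and Chil4 0.62 ± 0.81 (edgeR adjusted p = 0.658). Chil3 stood at 0.96 ± 0.64 (edgeR adjusted p = 0.348), and passed without the libraries under 2 M counts, at 1.90. S100a8 stood at 0.51 ± 0.30 (edgeR adjusted p = 0.276), at 0.72 and past the threshold without replicate 4 of the OVA arm without PM, and at -0.08 with the length and GC offset. Cyp1a1 stood at 0.34 ± 0.19 (edgeR adjusted p = 0.241), Saa3 at 0.35 ± 0.35 (edgeR adjusted p = 0.551) and Cxcl1 at -0.02 ± 0.23 (edgeR adjusted p = 0.979). Il13 did not pass the expression filter in the saline arm or for OVA without PM and was not tested there. In the OVA arm without PM it stood at 1.82 to 4.26 CPM apart from replicate 2 (0.173 CPM, 4 counts). The libraries of the saline arm without PM held 0 to 0.123 CPM of it. Retnla stood at 0.42 ± 0.46 (edgeR adjusted p = 0.586), and the directions of Il13, Ccl11 and Retnla turned negative with the length and GC offset (-0.02, -0.24 and -0.16). Without replicate 2 of the OVA arm without PM, Clca1 stood at -0.08 and Il13 at -0.15, and without replicate 2 of the OVA arm with PM Clca1 stood at -0.04.

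Higher with PM in the OVA arm was Wfdc21, a secreted whey acidic protein family gene (9.46 ± 4.30 CPM without and 22.9 ± 5.52 CPM with PM, log2 fold change 1.35 ± 0.21, edgeR adjusted p = 0.0135). Clec4e, a receptor of microbial glycolipids, was higher too (5.80 ± 1.52 CPM and 12.5 ± 2.70 CPM, log2 fold change 1.07 ± 0.20, edgeR adjusted p = 0.0153). Plvap, an endothelial diaphragm protein, fell from 403 ± 112 CPM to 182 ± 27.4 CPM (log2 fold change -1.17 ± 0.19, edgeR adjusted p = 0.0135). Oasl2, an interferon-stimulated gene, fell from 81.3 ± 15.8 CPM to 40.0 ± 10.6 CPM (log2 fold change -0.98 ± 0.17, edgeR adjusted p = 0.0146). Of 24 interferon-stimulated genes 8 fell, 18 adjusted over the list alone (adjusted p = 0.584 with an estimated correlation). Endothelial markers fell in 8 of 13 cases, 8 adjusted over the list alone, while 1 rose adjusted over it, with Cdh5, VE-cadherin, at -0.94 (adjusted p = 0.584 with an estimated correlation). Smooth muscle markers fell in 5 of 9 cases, 7 adjusted over the list alone, including Des, desmin (-1.02; adjusted p = 0.584 with an estimated correlation). Fibroblast and extracellular matrix genes fell in 5 of 14 cases, 6 adjusted over the list alone (adjusted p = 0.584 with an estimated correlation). Other genes with large falls were the stromal marker Cd248 (-1.72 ± 0.30), the matrix gene Ltbp4 (-1.47 ± 0.30), Foxs1 (-1.44 ± 0.25) and the laminin gene Lamc3 (-1.39 ± 0.26).

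Heart muscle genes moved with these groups. Of 12 measured, 10 fell with PM in the OVA arm, 12 adjusted over the list alone, at a median log2 fold change of -1.80 (adjusted p = 0.584 with an estimated correlation). Sln, sarcolipin of atrial muscle, stood at 4.86 ± 2.66 CPM without and 1.43 ± 1.27 CPM with PM, and Ttn, titin of striated muscle, at 13.1 ± 9.45 CPM and 2.08 ± 1.61 CPM. The levels did not follow PM in every library. Tnnt2, chosen after its values were seen, stood at 1.14 CPM in replicate 4 without PM (2 counts, others 23.6 to 59.1 CPM). In replicate 4 with PM it stood at 29.8 CPM (9 counts, others 4.08 to 17.4 CPM), while Ttn had 0 counts there. Both libraries held fewer than 2 M counts. In the mouse, heart muscle cells extend along the pulmonary veins into the lung. Ribosomal protein genes rose in 2 of 15 cases, 13 adjusted over the list alone (adjusted p = 0.584 with an estimated correlation). The median transcript length was 4553 nt for genes called lower, 1749 nt for genes called higher and 3257 nt for genes not called. The libraries with PM had a slope of log2 CPM on transcript length of -0.116 ± 0.0528 per doubling (SD, n = 5), and those without PM of 0.0827 ± 0.121 (SD, n = 6; exact permutation test, p = 0.0108, adjusted p = 0.0405). On GC content the slopes were -0.120 ± 0.107 and 0.0932 ± 0.103 per 10 points (SD, n = 5 and 6; exact permutation test, p = 0.0152, adjusted p = 0.0405).

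**Figure D2:**
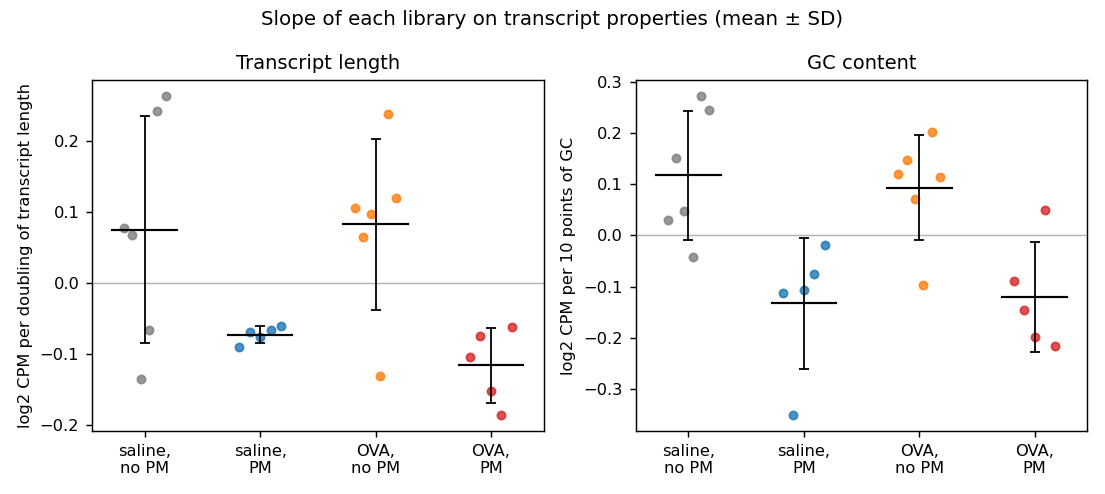
Slope of each library's log2 CPM on transcript length (left, per doubling) and on GC content (right, per 10 points), relative to the mean over the 22 libraries, by group, with the mean and SD of each group. The length slope averaged -0.0728 and -0.116 in the groups with PM and 0.0750 and 0.0827 in those without.

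Between the groups with and without PM of the OVA arm, edgeR's test called 1339 of 14657 genes, 332 higher and 1007 lower with PM. Scaled by library totals alone the count was 2054, with 184 higher and 1870 lower, and the median of all genes shifted by -0.106 on the log2 scale. DESeq2 called 519 higher and 994 lower, and the single fit of all 4 groups 575 and 1052. Camera called 12 of 45 lists, 0 of which held with an estimated correlation (0 of the 45 also at an unadjusted p under 0.05), and fry called 0 (11 at an unadjusted p under 0.05). No gene passed edgeR's test without replicate 1 or without replicate 6 of the OVA arm with PM (0 and 0 genes; 3207 and 3566 at an unadjusted p under 0.05), so that each gene call in this arm was lost without either library. Without replicate 5 of that group the higher genes numbered 213. The count was 410 without replicate 2 of that group, and 569, 524, 605 and 694 without replicates 1, 3, 5 and 6 of the OVA arm without PM. It was 3396 without replicate 4 of the OVA arm without PM (1376 of them higher) and 3472 without the 3 libraries under 2 M counts (1497 higher and 1975 lower), among them 1331 of the 1339. With the length and GC offset 339 genes were called, 74 higher and 265 lower, and 284 of the 1339 kept their call.

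The 2 PM comparisons share no library, but in both the libraries with PM carry the other series of sample numbers. A shared difference of preparation or run therefore cannot be told apart from PM in the agreement given here. Of the genes tested in both, 81 were higher with PM in both arms and 521 lower in both, where independent lists would share 18.1 and 74.4, and 0 were called in opposite directions by edgeR. Across genes the log2 fold changes had r = 0.687. With the length and GC offset r was 0.573, and 21 genes were higher and 113 lower in both, where independent lists would share 3.15 and 12.9. Clec4e was among the genes higher in both, at log2 fold changes of 1.92 ± 0.18 and 1.07 ± 0.20 in the saline and OVA arms.

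Whether the PM effect differed between the arms was tested directly as the difference between the log2 fold changes. Saa3 rose with PM in the saline arm and stood at 157 ± 84.3 CPM (SD, n = 6) without and 197.9 ± 106 CPM (SD, n = 5) with PM in the OVA arm, a difference of -5.10 ± 0.58 between the log2 effects (SE, edgeR adjusted p = 2.6e-05). Cxcl3 stood at 9.0 ± 2.5 CPM and 14.4 ± 2.59 CPM in the OVA arm (difference -3.94 ± 0.38, edgeR adjusted p = 3.26e-06). Irg1 had a fitted log2 fold change of -0.09 ± 0.33 with PM in the OVA arm (edgeR adjusted p = 0.899), and the difference was -4.66 ± 0.53 (edgeR adjusted p = 2.6e-05). Its mean there, 4.62 ± 3.63 CPM with and 2.77 ± 0.539 CPM without PM, was raised by replicates 4 and 5 with PM, which held 3 and 7 counts of it. Lcn2 differed by -2.14 ± 0.38 (edgeR adjusted p = 0.014) and Cxcl1 by -2.03 ± 0.35 (edgeR adjusted p = 0.0115). In all, 14 genes passed, each with a lower log2 effect in the OVA arm, and 571 of 14942 had an unadjusted p under 0.05. A lower effect can have the opposite sign, as for Rsad2 (0.91 in the saline arm and -0.84 in the OVA arm). Of the 14, 0 were called lower with PM in the OVA arm. All 14 were higher with PM in the saline arm, 2 of them also in the OVA arm, Cxcl3 and Orm1, which were chosen after their values were seen, and 12 did not pass there. Without PM, 13 of the 13 that could be tested were already higher in the OVA arm than in the saline arm, and Orm2 was not tested there (79 counts against 5). The allergy genes Muc5ac (-2.67 ± 0.82, edgeR adjusted p = 0.687) and Ccl11 (-1.25 ± 0.49, edgeR adjusted p = 1) did not pass, nor did Retnla, Clca1, Chil4, Il13, Chil3, S100a8 and Cyp1a1 (edgeR adjusted p = 0.617, 1, 1, 1, 1, 1 and 0.878), but Muc5ac passed without replicate 2 of the OVA arm without PM, at -2.905.

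**Figure D3:**
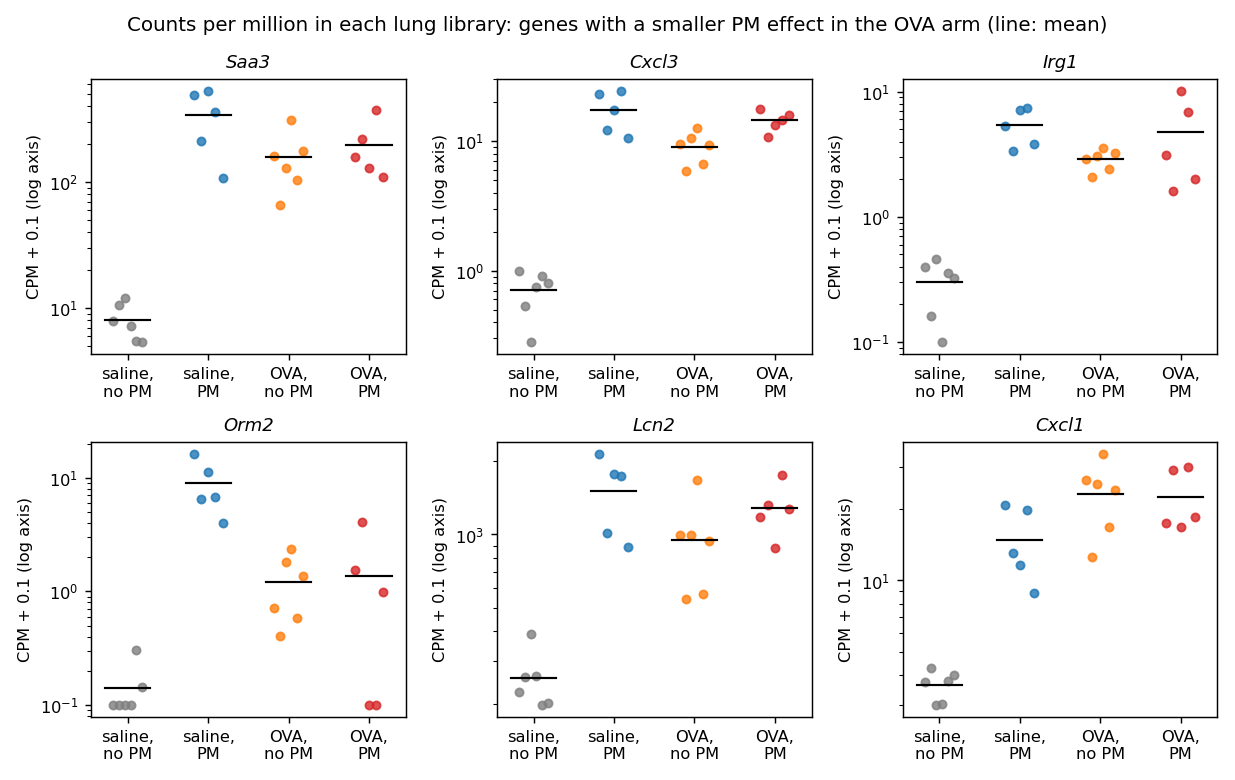
TMM-scaled counts (CPM, log axis, with 0.1 added) of Saa3, Cxcl3, Irg1, Orm2, Lcn2 and Cxcl1 in each of the 22 libraries, by group, with a line at each group's mean. Saa3 averaged 7.97 and 338.8 CPM without and with PM in the saline arm and 157 and 197.9 CPM in the OVA arm.

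The interferon-stimulated genes had a median difference between the PM effects of -0.83 on the log2 scale. Of 24, 1 passed (Rsad2, -1.73 ± 0.30, edgeR adjusted p = 0.014) and 21 adjusted over the list alone, and the list held its call (adjusted p = 0.00397 with an estimated correlation). NF-kB-driven cytokines and neutrophil chemoattractants had a median difference of -1.01, with 4 of 18 past the threshold and 9 adjusted over the list alone (adjusted p = 0.00102 with an estimated correlation). Camera called 19 of 45 lists for the difference, 17 of them towards a lower log2 effect in the OVA arm, and 2 held with an estimated correlation. The number of genes was 22 by DESeq2, all lower, and 14 of these were the edgeR calls. It was 27 without replicate 2 of the OVA arm without PM, 8, 9 and 9 without replicates 1, 5 and 6 of the saline arm without PM, 9 and 8 without replicates 1 and 5 of the saline arm with PM, and 8 without replicate 6 of the OVA arm with PM. An effect of preparation or sequencing run drops out of this difference only where it changes a gene by the same factor in both arms. The labels do not state whether the libraries with PM of both arms shared a run.

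The last comparison asked how the OVA arm differed from the saline arm when both received PM. Ccl8 rose from 26.9 ± 12.4 CPM (SD, n = 5) to 529 ± 162 CPM (SD, n = 5), a log2 fold change of 4.36 ± 0.29 (SE, edgeR adjusted p = 1.07e-07). Clca1 rose from 197 ± 177 CPM to 5262 ± 3057 CPM (log2 fold change 4.76 ± 0.78, edgeR adjusted p = 0.000263). Muc5ac rose from 5.71 ± 4.14 CPM to 115.4 ± 65.5 CPM (log2 fold change 4.44 ± 0.37, edgeR adjusted p = 8.66e-07). Arg1, the arginase of alternatively activated macrophages, rose from 11.1 ± 3.71 CPM to 91.6 ± 63.5 CPM (log2 fold change 3.13 ± 0.33, edgeR adjusted p = 5.64e-06). The cytokine genes Il10 (3.03 ± 0.45) and Il13 (2.78 ± 0.44) rose too, as did Chil4 (6.10 ± 0.69), Chil3 (4.01 ± 0.44), Retnla (3.13 ± 0.48) and Ccl11 (2.33 ± 0.27). S100a8 (-0.22 ± 0.16, edgeR adjusted p = 0.388) and Cyp1a1 (0.14 ± 0.16, edgeR adjusted p = 0.59) did not pass. Saa3 had a log2 fold change of -0.77 ± 0.36 (edgeR adjusted p = 0.148), and passed without replicate 6 of the saline arm with PM, at -1.005, and without replicate 5 of the OVA arm with PM, at -1.09. Cxcl1 stood at 0.55 ± 0.23 (edgeR adjusted p = 0.0961), and passed without replicate 1 or 5 of the saline arm with PM, at 0.67 and 0.71.

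All 18 proliferation genes rose in the OVA arm with PM, 18 adjusted over the list alone, with Mki67 at a log2 fold change of 2.42 and Hmmr at 2.49 (adjusted p = 0.0546 with an estimated correlation). Mucous cell genes rose in 12 of 12 cases, 12 adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). Eosinophil markers rose in 8 of 9 cases (8 adjusted over the list alone), including the eotaxin receptor gene Ccr3 at 1.95 and Alox15 at 2.37 (adjusted p = 0.124 with an estimated correlation). Of 13 monocyte and interstitial macrophage markers 10 rose, while adjusted over the list alone 10 rose and 1 fell (adjusted p = 0.0546 with an estimated correlation). Of 12 alternatively activated macrophage genes 10 rose, 12 adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). Interferon-stimulated genes rose in 12 of 24 cases, 14 adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). All 12 alveolar type 1 cell markers fell, 12 adjusted over the list alone, including the water channel gene Aqp5 (-0.57; adjusted p = 0.128 with an estimated correlation). Endothelial markers fell in 12 of 13 cases, 12 adjusted over the list alone, with the VEGF receptor gene Kdr at -0.91 and Cdh5 at -0.78 (adjusted p = 0.124 with an estimated correlation), and heart muscle genes in 9 of 11, 10 adjusted over the list alone (adjusted p = 0.392 with an estimated correlation). Genes with large falls in the OVA arm with PM were Hpx, the haem carrier hemopexin (-2.61 ± 0.44), and Asgr1 (-2.27 ± 0.29).

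With PM in both arms, edgeR called 3244 of 14250 genes, 1880 higher and 1364 lower in the OVA arm. The lower genes numbered 874 without replicate 1 of the OVA arm with PM and 982 in the single fit of all 4 groups. Camera called 20 of 45 lists, 0 of which held with an estimated correlation (11 at an unadjusted p under 0.05, and 23 past the threshold by fry). Scaled by library totals alone, 1509 genes were higher and 1922 lower. The OVA effects with and without PM share no library, and 1410 genes were higher and 740 lower in both, where independent lists would share 268 and 128, while 3 were called in opposite directions. Their log2 fold changes had r = 0.863 across genes.

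**Figure D4:**
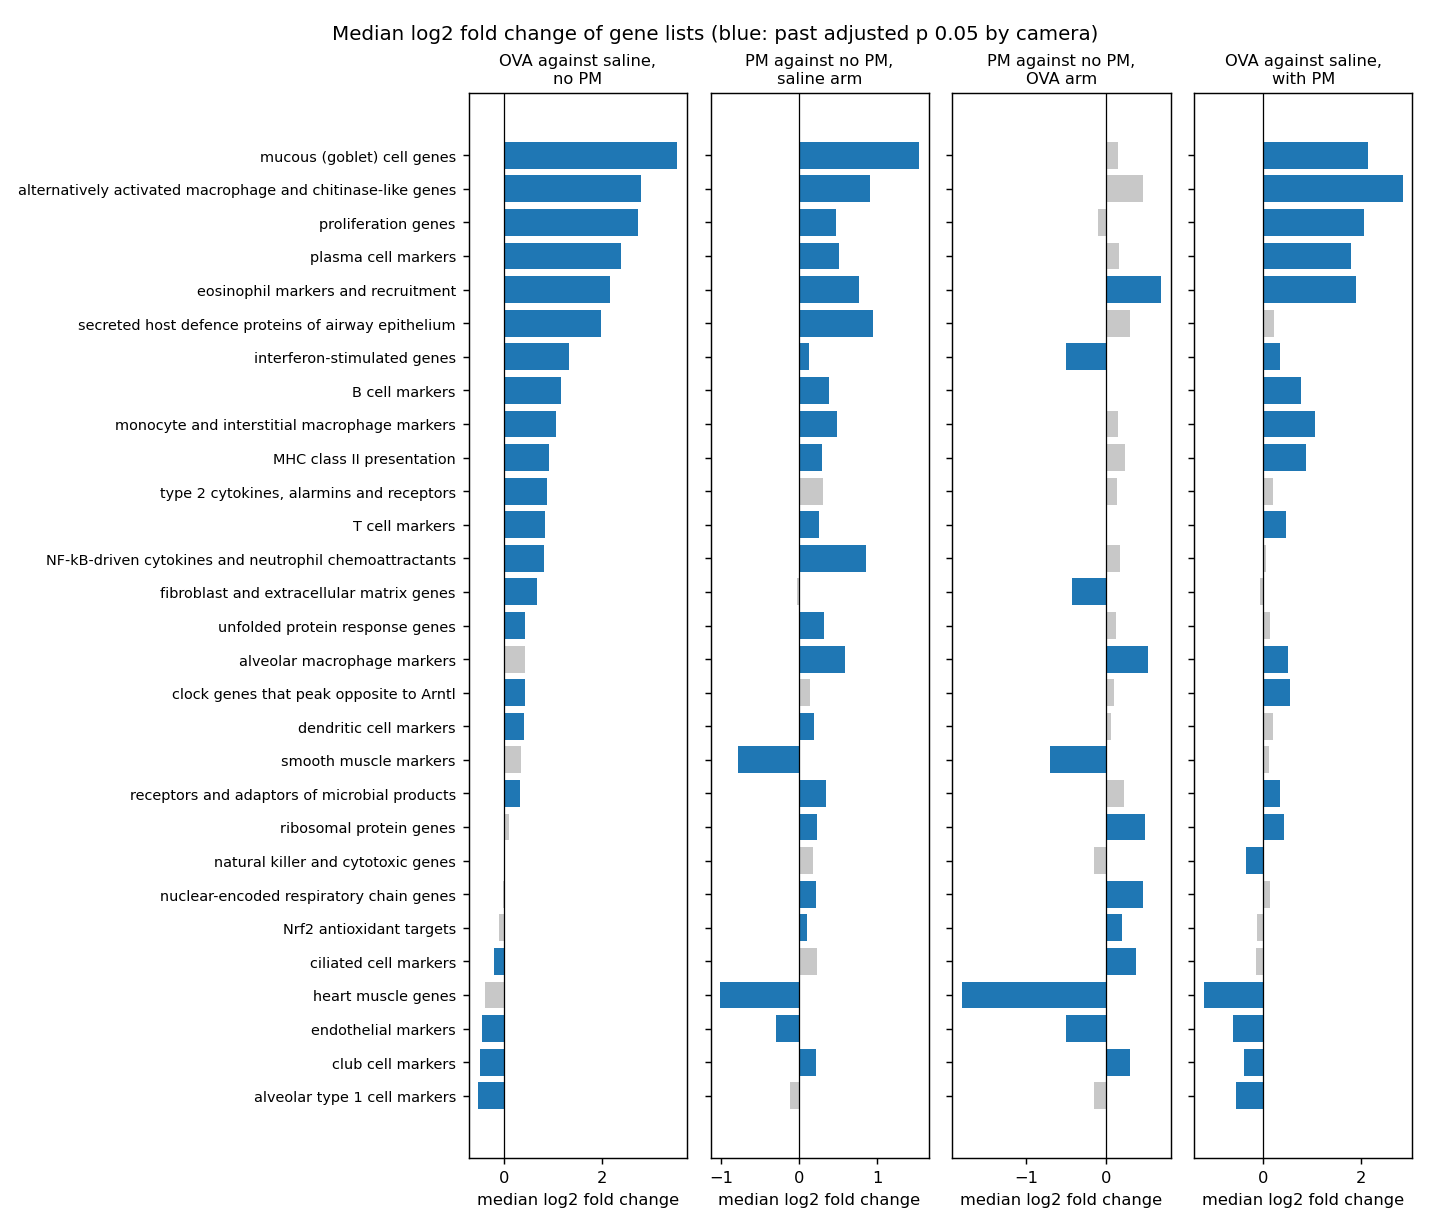
Median log2 fold change of the gene lists that camera called in at least 2 comparisons, as bars, in the 4 comparisons of groups. Blue bars passed an adjusted p of 0.05 with a preset correlation, which mostly did not hold with an estimated one, and grey bars did not. Proliferation genes rose in 18 of 18 cases in both OVA comparisons, and heart muscle genes had a median of -1.80 with PM in the OVA arm.

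The authors' deposited tables give their own test for 3 of these comparisons. In the authors' deposited table for OVA without PM, 4133 genes passed an adjusted p of 0.05, 2267 higher and 1866 lower, and it held 3419 of the edgeR calls (98.9%). In the authors' deposited table for PM in the saline arm, 2824 genes passed, 1128 higher and 1696 lower, with 1840 of the edgeR calls (98.8%). In the authors' deposited table for PM in the OVA arm, 2074 genes passed, 767 higher and 1307 lower, with 1243 of the edgeR calls (92.8%). Each of these shared calls in the 3 authors' deposited tables had the same sign.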

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

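The test for values far from their group (Dixon's test) and the test of the difference between the PM effects were planned. Dixon's test marked 12 of 76 groups of values, where chance alone marks about 1 in 20, and a marked value shows only that 1 library lay apart.

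Replicate 4 of the OVA arm without PM had 15277 genes detected, against 16759 to 17632 in the other libraries of its group, and it held 1.84 M counts. Replicate 2 of the saline arm with PM had a slope on GC content of -0.352 per 10 points, against -0.112 to -0.019 in the others.

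Replicate 2 of the OVA arm without PM stood low in several allergy genes, with Muc5ac at 21.03 CPM (others 129 to 260.4), Clca1 at 668.6 CPM (4436 to 7622), Retnla at 2030 CPM (7316 to 14900) and Chil4 at 5.14 CPM (400 to 1012). Replicate 4 of the OVA arm with PM, the library with 0.302 M counts, stood low in Muc5ac at 9.95 CPM (94.6 to 168), Clca1 at 417.8 CPM (4274 to 8027), Ccl11 at 9.95 CPM (47.2 to 67.9), Retnla at 2049 CPM (13370 to 16670) and Chil4 at 13.3 CPM (641.4 to 1668). Its Muc5ac, Ccl11 and Chil4 values were 3, 3 and 4 counts. Il13 in replicate 2 of the saline arm without PM was at 0.123 CPM, against 0 to 0.0444 in the others. This was 2 counts against 0 or 1, too few to tell apart.

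The log2 PM effect was lower in the OVA arm than in the saline arm in 14 genes by edgeR, given as the difference of the log2 fold changes. These were Orm2 (-5.93), Saa3 (-5.10), Irg1 (-4.66), Cxcl3 (-3.94), Cxcl5 (-3.44), Orm1 (-2.83), Ccl7 (-2.77), Lcn2 (-2.14), Cxcl1 (-2.03), Cxcl13 (-2.03), Serpina3n (-1.86), Tnf (-1.82), Rsad2 (-1.73) and Steap4 (-1.17). Genes of this list outside the fixed rule were chosen after their values were seen. The size for Orm2 (SE 0.959) rests on a base near 0, with at most 4 counts in a library of the saline arm without PM. Replicates 4 and 5 of the OVA arm with PM held 0 counts of Orm2.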

How the results depend on the processing

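The offset for transcript length and GC and the fits without the libraries under 2 M counts were chosen after the results were seen, and the cause of the changes below was not tested unless stated.

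The genes called for PM in the OVA arm numbered 1339, 2054 scaled by library totals, 339 with the offset and 3472 without the libraries under 2 M counts. DESeq2 called 22 genes for the difference between the arms, against 14. With an estimated correlation the lists called by camera numbered 1 (OVA without PM), 0 (PM in the saline arm), 0 (PM in the OVA arm), 0 (OVA with PM) and 2 (difference), and fry called 0 for PM in the OVA arm and 2 for the difference. At an unadjusted p under 0.05 the estimated correlation gave 11, 9, 0, 11 and 7 lists, and fry 11 and 5.

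Leaving out 1 library gave 490 (without saline arm with PM, replicate 5) to 4112 genes (without saline arm without PM, replicate 3) for PM in the saline arm. For PM in the OVA arm it gave 0 by edgeR (without OVA arm with PM, replicate 1 or 6; 3207 and 3566 at an unadjusted p under 0.05) to 3396 (without OVA arm without PM, replicate 4), and for the difference 8 (without saline arm without PM, replicate 1) to 27 (without OVA arm without PM, replicate 2).

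Some directions reversed. Among results that had passed, these were, with the offset, the list of nuclear-encoded respiratory chain genes (-0.0249) for PM in the saline arm and its members Ndufa1 (-0.11) and Uqcrb (-0.21) for PM in the OVA arm. The others had not passed. With the offset they were S100a8 (-0.10) for PM in the saline arm, and Il13 (-0.0244), Ccl11 (-0.24), Retnla (-0.16) and S100a8 (-0.0806) for PM in the OVA arm. Without the libraries under 2 M counts, Cxcl1 stood at 0.0183 for PM in the OVA arm and Chil3 at 0.91 for the difference. Leaving out 1 library, log2 values for PM in the OVA arm ran from -0.0753 to 0.45 (Clca1), -0.15 to 0.58 (Il13) and -0.20 to 0.12 (Cxcl1), and for the difference from -0.48 to 0.62 (Chil3) and -0.0246 to 0.37 (S100a8).

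Replicate numbers did not pair the libraries throughout, and in each comparison 1 library correlated best with its own number. The correlation between libraries of the same number ran from -0.19 to 0.725 (OVA without PM), -0.226 to 0.168 (PM, saline arm), -0.272 to 0.187 (PM, OVA arm) and -0.116 to 0.219 (OVA with PM), over 0.1 in 3 of 6, 2 of 5, 1 of 5 and 1 of 4. Between the groups without PM, replicates 4 and 5 had 0.635 and 0.725, while replicates 1, 2 and 3 had 0.0118, 0.0299 and -0.19. Replicates 4 and 5 of the OVA arm nevertheless correlated more with a saline arm library of another number. Only replicate 6 (0.243) correlated best with its own. These values are thus weak grounds for a batch that goes with the number, which is not excluded there. With the numbers as a block, 4238 genes were called for OVA without PM (3456 without the block) and 3083 for OVA with PM (3244). The block gave 3189 genes for PM in the saline arm and 561 in the OVA arm, where Cxcl1 stood at 0.10, and Chil3 at 0.22 for the difference.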

Other observations

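Some genes of the circadian clock differed between the OVA and saline arms, in both directions. Of 15 clock genes in the fixed list, 7 were higher and 2 lower in the OVA arm without PM (7 and 4 adjusted over the list alone), and 6 were higher and 3 lower with PM (7 and 4 adjusted over the list alone), and camera did not call the list in either comparison (adjusted p = 0.497 and 0.0932). The genes named next were chosen after their values were seen. Arntl, an activator of the clock, was lower in the OVA arm by a log2 fold change of -0.96 ± 0.11 without PM (edgeR adjusted p = 3.71e-05) and -0.96 ± 0.12 with PM (edgeR adjusted p = 2.8e-05). The repressor gene Bhlhe41 (1.21 and 0.80) and the output gene Dbp (0.93 and 0.87) were higher in both. Per2 (0.44 and 0.73) and Per3 (0.48 and 0.62) were higher too, while Nr1d1 did not pass without PM (0.11) and was lower with PM (-0.36). The time of day of sampling was not given in the sources used here, and a difference in it was not tested.

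Of the tests below, the offset for transcript length and GC, the fits without the libraries under 2 M counts, the test of genes already raised by OVA and the tests for a male animal and for 1 X chromosome were chosen only after the result was seen.

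Replicate 5 of the OVA arm without PM had 5 Xist counts (0.605 CPM), where the other 21 libraries had 215 to 429 CPM. Its 4 Y-linked genes had 0 CPM together, against a floor of 0.396 CPM for 3 counts, which argued against a male animal. Other X-linked genes lay 0.029 on the log2 scale above the autosomal median, which argued against 2 active X chromosomes. The 6 X-escape genes lay below their level in the other libraries of the group (median log2 difference -0.55, the lowest of 22 libraries), so that 1 X chromosome may explain the library and stays open as a hypothesis. Replicate 5 of the OVA arm with PM, which had Xist, lay as far in the other direction on the same genes (0.562), so that this measure is weak evidence.

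Genes lower with PM were weighed against a trend of the libraries on transcript length and GC. With the offset, 43.1% of those called lower in the saline arm and 22.7% in the OVA arm were still called lower, and the median ratios of their log2 fold changes were 0.583 and 0.618, so that such a trend may account for part of them, although the offset can also absorb real change. In the simulated counts a length slope of -0.15 with no changed gene gave 5 and 19 calls in these comparisons, where the measured differences in slope were -0.148 and -0.199. Each library of the group was given the same slope, and the dispersions, fitted on the real libraries, already held the spread of the trend between them. No GC slope was planted there. The simulation therefore covers length alone and cannot tell how many calls the real trend gives. The heart muscle list had a median of -2.0 with the offset in the OVA arm, which argued against the trend as its cause, and the libraries under 2 M counts were no cause of the falls in the OVA arm (median ratio without them 1.05). How much of the heart muscle sleeve of the pulmonary veins each sample held, and a difference of preparation or run between the libraries with and without PM, stay open.

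The lower log2 PM effect in the OVA arm was kept in 14 of 14 genes with the offset, which argued against the trend as its cause. Without the libraries under 2 M counts 10 of the 14 genes kept their call. The median ratio of the differences without those libraries was 1.0, which argued against them as the cause of its size. Without PM, 13 of the 13 genes tested there were already higher in the OVA arm (Orm2 was not tested), so that a response already raised by the allergen is a candidate explanation. The libraries without PM enter both numbers, which tilts this count upward.

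Other splits of the libraries tested whether chance could give as many genes, with 100 splits per comparison. Chance can be excluded for OVA without PM (1 split with as many, 3456 genes, highest other 2595) and OVA with PM (1 split, 3244 genes, highest other 1465). For PM in the saline arm (2 splits, 1862 genes, highest other 3256) and PM in the OVA arm (2 splits, 1339 genes, highest other 3330) the share of splits lay under 0.05. Since another split called more genes in each arm, this share does not show that PM sets the count. For the difference between the arms (2 splits, 14 genes, highest other 3170) the splits cannot decide. They exchanged PM labels within each arm, which stands for no PM effect in either arm and not for equal effects. In these 3 comparisons another split called more genes than the real one. These splits largely followed PM, but in the saline arm the split followed the length slope without exception. In the OVA arm the larger split exchanged only replicate 4 of each group, 2 of the 3 libraries under 2 M counts, and without replicate 4 of the OVA arm without PM 3396 genes were called. That library had the only negative length slope of its group (-0.132, others 0.065 to 0.239), while replicate 4 with PM had -0.153. In the saline arm the larger split parted the libraries as PM did apart from replicates 3 and 4 without and 6 with PM. It also parted them by length slope, at -0.136 to -0.066 against -0.061 to 0.264. For the difference the larger split exchanged 8 of the 11 labels of the OVA arm and 4 of the 11 of the saline arm, so that the contrast mostly added the PM effects of the arms. These counts point to a structure of the samples that goes partly with PM and partly with the length slope, and the splits cannot tell these apart.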
